A study of Drosophila melanogaster with 8 samples.

How the data were processed

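Total RNA from S2 cells was labelled with biotin and hybridised to 8 Affymetrix arrays, 4 of an older design (called the older array type here) and 4 of the later Drosophila 2.0 design (the newer array type). The labels put 2 older arrays in a group treated with ethanol and cycloheximide (EtOH), 2 newer arrays in a group called V with cycloheximide (V), and 4 arrays, 2 of each type, in a group treated with dexamethasone and cycloheximide (DEX). What V stands for is not stated in the labels, and it was used as the control of the DEX arrays in its own table, as EtOH was in the other. The deposited table of each array type gives 1 intensity per probe set and array. Per the submitters' processing notes the intensity values were made with GCRMA, which corrects the background with the help of probe sequence, normalises by quantiles and summarises the probes of a set; its version is not given in the sources used here. GCRMA gives values on a log2 scale, whereas the deposited intensity values are not on a log scale, and the base used to leave that scale is not given in the sources used here. No column was without a sample.

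The log2 of each value was taken with no pseudocount, since every value was above 0. Control probe sets, 44 on the older and 183 on the newer array type, were left out of the tests. Probe sets were tested where the mean log2 value over the fitted arrays was at least 4, a value of 16 on the deposited scale. Each array type was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05; each such fit has 2 residual degrees of freedom and leans on the variance shared across probe sets. Because the tables were normalised separately, no level was set against a level of the other table. For the fit of both array types, each gene was represented on each type by its probe set with the highest mean, array type was a block, and DEX was compared with control within types, 4 arrays against 4. A further limma fit with an interaction term tested the difference of the 2 effects, given as the newer minus the older type. Every adjusted p in the text is from limma unless a gene list test is named.

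Probe sets were named through the platform annotation, with symbols updated through the RefSeq genes of Drosophila melanogaster assembly Release 6 plus ISO1 MT. On the older type 12444 probe sets had 1 gene symbol, 327 had several and 1239 had none, and 12394 of those with 1 symbol matched a current gene. On the newer type the numbers were 13647, 402 and 4903, and 13544 matched. No gene was named from a probe set with several symbols. Probe sets whose identifiers end in _s_at, _x_at, _i_at, _f_at or _a_at can read more than 1 transcript or gene, and genes read through _s_at or _x_at are uncertain. On the newer type these are vri, Pdp1, Clk, MFS14, CtsL1, CG7530, CG6231, Akt, Amun, exu and Fer1HCH, and on the older type the brightest probe set of tim, so their differences between types are uncertain too. No genome was used and no coordinates are given; the RefSeq gene order served only to say which genes are neighbours.

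The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the measured members of the core clock list, then genes past the threshold in the fit of both array types with no overlap between groups within either type (up to 15 higher and 10 lower), filled to 10 with the smallest p-values and stated as not passing where fewer qualified. It added up to 3 members with the smallest adjusted p from each other list, and, for features measured on 1 array type only, up to 5 higher and 3 lower past the threshold without overlap. Since 0 genes qualified in the fit of both array types, the genes changed on the older type and the genes whose effect differed between types were also named, by their calls and after their values were seen. The 21 lists were core clock feedback loop; clock kinases, phosphatases and ligases; rhythmic clock output; bHLH-PAS factors; Hairy/E(spl)-type repressors and Notch targets; ecdysone response; immune response; heat shock; ER stress; AP-1 and JNK response; cell cycle; glycolysis; apoptosis; cytoskeleton and adhesion; markers of haemocytes, neurons, muscle, fat body with gut, and germline; ribosomal proteins; and cytochrome P450 enzymes. They were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry.

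No columns held identical values. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. In the fit of both types that spread includes any disagreement between the types. The number of arrays, 2 per group and type, limits the precision. The fits were tested on simulated data with 200 changed genes, drawn from the real means and moderated variances. At an adjusted p of 0.05 the older type's fit recovered 90.8% of changes of 1 on the log2 scale, and the newer type's fit 25.9% of changes of 1, 73.5% of changes of 2 and 86.5% of changes of 3. The fit of both types recovered 94.0% of changes of 1, and the interaction 94.6% of effects of 1 turned between types. For the fit of both types the simulated change was the same on each type. Its rate therefore does not cover genes whose effects oppose each other. False calls made up 7.82% of the calls on the older type, 4.35% on the newer, 1.81% in the fit of both and 8.79% in the interaction. The simulated features varied independently of each other, unlike real genes. With 200 changed genes the adjustment is also less strict than where few genes pass, so these rates may overstate recovery in the real data. On the newer type, for example, vri at -2.07 ± 0.16 (SE) was not called. Alternatives were other filters, variance models, normalisations, thresholds, probe set rules, array weights, the replicate number as a block, and leaving out each array in turn. The natural log scale with a minimum of 4 there, an F test without direction, list tests per array type and effects with the variance of all 8 arrays were added after seeing the data.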

Results

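CLKGR is a fusion of the circadian transcription activator CLK with the hormone-binding part of the glucocorticoid receptor, which dexamethasone (DEX) releases. Cycloheximide (CHX) blocks translation, so a comparison of DEX with control in its presence asks which transcripts respond without new protein. The fusion was studied in S2 cells, a Drosophila melanogaster line of embryonic origin with traits of haemocytes. RNA was read on 8 arrays of 2 types. On the older type, 2 arrays were labelled DEX and 2 EtOH, and on the newer type 2 were labelled DEX and 2 V, all with CHX.

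The deposited intensities of single probe sets ran up to 2128800 on the older and 5129390 on the newer type. Median values per array lay between 27.0 and 28.8 on the older type and between 21.5 and 22.4 on the newer. Between 67 and 70 probe sets per array on the older type, and between 139 and 142 on the newer, exceeded 65535, the top of a 16-bit scanner. The highest value per array was 20.8 to 22.3 on log2, above the 16 of such a scanner, and 14.4 to 15.5 on the natural log. The hybridisation controls BioB, BioC, BioD and Cre, at nominal concentrations of 1.5, 5, 25 and 100 pM, rose with slopes of 1.30 to 1.45 on the log2 of the value and 0.902 to 1.01 on its natural log. These controls are read by different probe sets, which may bind unequally. The mean log2 steps from BioB to BioC, BioC to BioD and BioD to Cre were 1.26, 2.65 and 4.54 on the older type. On the newer type they were 1.87, 3.32 and 3.04. The values above 65535 on every array argue against base 2, provided that the scanner was of 16 bits and no scaling followed. Which other base was used stays open, since unequal binding bears on the slopes. If the base is e, each log2 difference below is to be multiplied by 0.693, and the p-value of a given fit stays as it is.

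**Figure D1:**
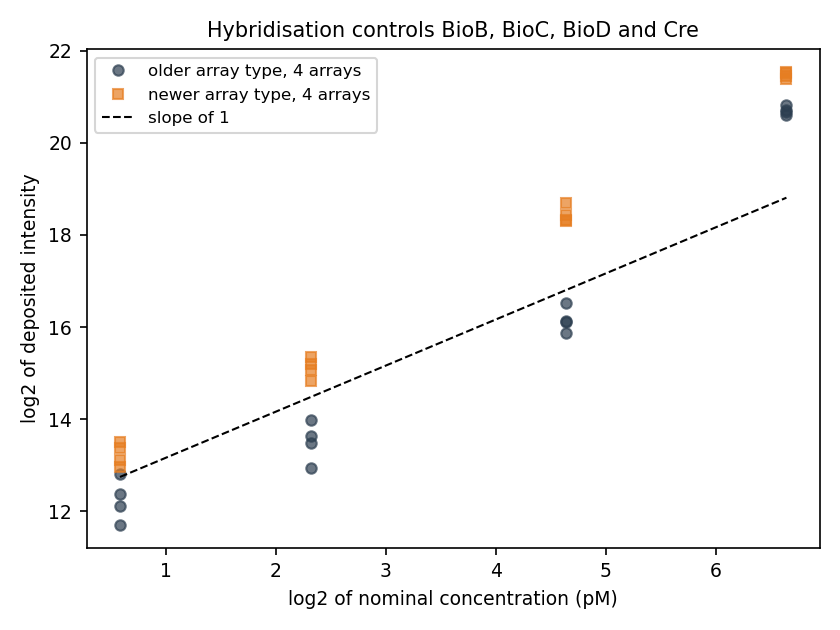
Log2 of the deposited intensity (vertical axis) of the hybridisation controls against the log2 of their nominal concentration in pM (horizontal axis), 1 point per control and array, with a dashed line of slope 1. Fitted slopes per array run from 1.30 to 1.45.

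On the older array type, 4 genes of the clock feedback loop, vri, cwo, Pdp1 and tim, had a probe set that rose with DEX. The largest difference was in vri, which encodes a bZIP repressor of Clk transcription: log2 intensity went from 6.68 ± 0.18 (SD, n = 2) with EtOH to 10.72 ± 0.43 with DEX, a difference of 4.04 ± 0.26 (SE, limma adjusted p = 0.0056), or 16.5-fold as deposited and 6.97-fold on base e. The bHLH repressor gene cwo rose by 3.51 ± 0.27 and by 2.91 ± 0.29 on 2 probe sets (adjusted p = 0.0112 and 0.0297), and Pdp1, a bZIP activator of Clk transcription, by 2.34 ± 0.17 (adjusted p = 0.0104). The clock gene tim, partner of per in the repressor complex, rose by 1.96 ± 0.13 on 1 probe set (adjusted p = 0.0063), while its brightest probe set, which ends in _s_at and is uncertain, differed by 2.62 ± 0.41 (adjusted p = 0.143) and another by -0.04 ± 0.09. These calls depend on the scaling, though the differences kept their size: with median centring only that of tim passed (adjusted p = 0.0497, vri 0.0616, Pdp1 0.0536, cwo 0.123 and 0.180), and with quantile normalisation repeated none did (vri 0.116, tim and Pdp1 0.0872, cwo 0.148 and 0.192). The Clk probe set stood at 11.19 ± 0.28 with EtOH and 10.30 ± 0.21 with DEX, a difference of -0.89 ± 0.22 that did not pass (adjusted p = 0.420). Whether the Clk probe sets of either array type also read the transcript of the CLKGR fusion was not tested, so their values may not be those of the cells' own gene. cyc, the partner of CLK, differed by 0.08 ± 0.20, and per and cry lay below the minimum, at log2 2.52 and 3.95 with EtOH.

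In all, 27 of 10250 probe sets changed on the older type, 22 higher and 5 lower with DEX, and 600 lay at an unadjusted p under 0.05 where 512 are expected by chance. The called probe sets named 18 higher and 4 lower genes. MFS14, of the major facilitator family of transporters, rose by 3.48 ± 0.13 (adjusted p = 0.0016), CG15096 rose to 6.49 from an EtOH level of 3.38 near the floor, so the size is not resolved, the trehalose transporter gene Tret1-1 rose by 2.42 ± 0.14 and Orct2, an organic cation transporter gene, by 2.68 ± 0.19. The Notch-responsive E(spl) genes E(spl)m6-BFM and E(spl)mbeta-HLH rose by 2.19 ± 0.17 and 1.81 ± 0.19. Also higher were CG13868 (by 2.84), CG3764 (by 2.32), the stress gene Gadd45 (by 2.24), Prps, for phosphoribosyl pyrophosphate synthesis (by 2.16), Fmo-2 (by 1.67), the cathepsin gene CtsL1 (by 1.48) and the chromatin remodeller gene Chd3 (by 0.98), with adjusted p between 0.0056 and 0.0475. CG3857 fell by 1.83, CG13917 fell by 1.24, and the adenylyl cyclase gene rut fell by 0.76 on a probe set that can read several genes. CG8630 was also lower, at 4.75 with EtOH and 3.94 with DEX, under the minimum of 4, so the size is not resolved. Its 2 EtOH arrays held the same value, an SD of 0 that favours a call, so the call is uncertain too. Among features measured on this type only, CG7369 rose by 0.92 and an unnamed probe set fell by 1.39. A probe set annotated to 2 genes, 1 of them counted above, and so left unnamed, rose by 3.41. With either EtOH array left out 0 probe sets passed. Without a DEX array the fit took the variance as known from all probe sets, so its counts are not comparable; the 27 had the same sign in all 4 cases. Median centring left 8 calls (MFS14 and Tret1-1 with 2 probe sets each, CG15096, CG13868, tim and the probe set annotated to 2 genes) and repeated quantile normalisation 4 (MFS14, Tret1-1, CG15096 and the same probe set), all higher with DEX.

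On the newer array type the same clock transcripts were lower on the arrays labelled DEX than on those labelled V, and none passed in the fit of this type alone. With the variance of all 8 arrays, added later, the brightest probe sets of vri and Pdp1 passed (adjusted p = 0.0391 and 0.0313). Those of cwo (0.172) and tim did not. The values that follow are from the fit of this type alone. vri stood at 12.53 ± 0.17 (SD, n = 2) on arrays labelled V and 10.47 ± 0.18 on arrays labelled DEX, a difference of -2.07 ± 0.16 (SE, adjusted p = 0.849) on an uncertain _s_at probe set. tim was at 6.25 with V on 1 probe set (adjusted p = 0.318) and at 5.01 and 7.58 on the V arrays on its brightest. Its DEX-labelled arrays lay at 3.72 and 3.76 on these, near the level of cry and under the minimum of 4, so the size of the tim difference and its error are not resolved. The difference was -2.14 ± 0.25 for Pdp1 (uncertain, _s_at) and -2.90 ± 0.66 and -2.28 ± 0.65 for 2 probe sets of cwo (adjusted p = 0.865 each). Clk was at 8.02 with V and 8.35 with DEX, a difference of 0.33 ± 0.15 (uncertain, _s_at), cyc differed by -0.05 ± 0.11 and per by -0.01 ± 0.10, and cry lay below the minimum at 3.73.

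limma called 0 of 12436 probe sets in the fit of the newer type alone, and 439 lay at an unadjusted p under 0.05 where 622 are expected by chance. With the variance of all 8 arrays, added later, 14 of 8404 genes passed on this type, 13 lower and 1 higher on arrays labelled DEX. In the fit of this type alone, 10 genes measured on both types had a p under 0.001. All 10 were lower on arrays labelled DEX, and 9 were higher with DEX on the older type. They included MFS14 at -3.38 (uncertain, _s_at), phu at -3.49, Tret1-1 at -2.42, CG3348 at -2.17 and ClC-a, a chloride channel gene, at -1.87, which was also lower on the older type (-0.38).

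**Figure D2:**
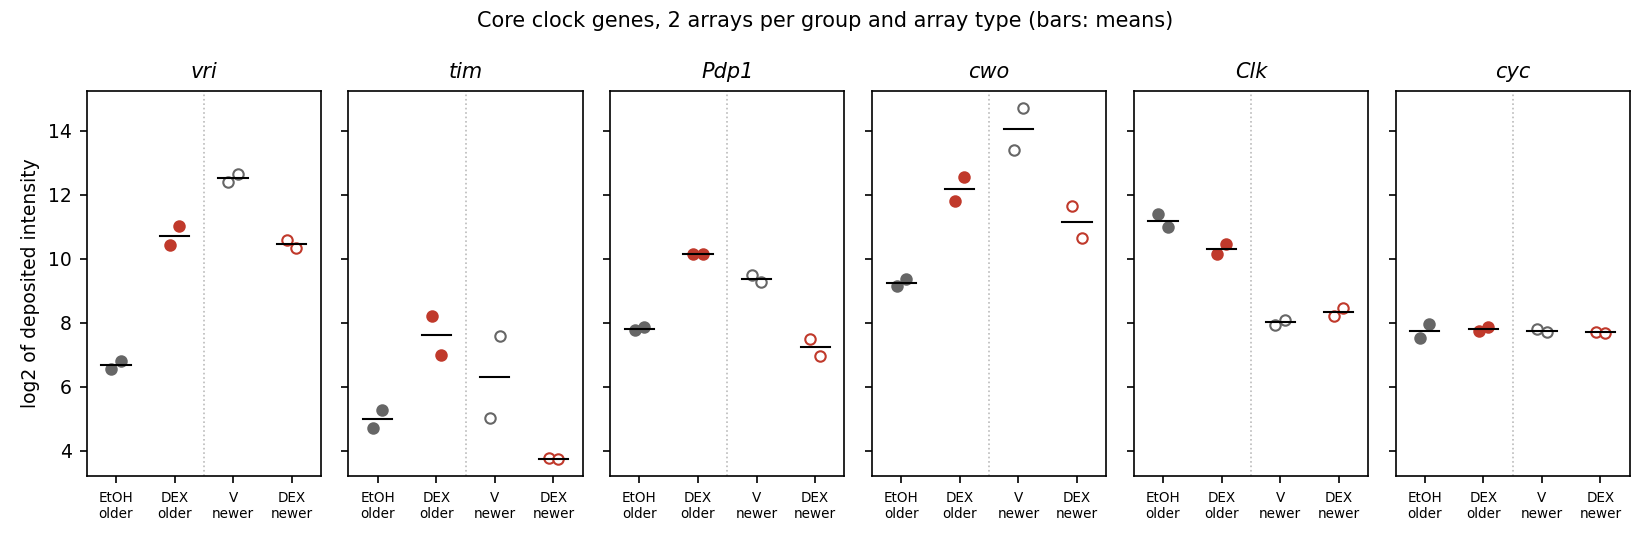
Log2 of the deposited intensity (vertical axis) of 6 core clock genes on each array, by group and array type, from the brightest probe set of each type; points are arrays (filled, older type; open, newer type) and bars are means of 2. The arrays labelled DEX lie above EtOH on the older type and below V on the newer type for vri, tim, Pdp1 and cwo, and levels are not comparable between types.

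A direct test of the difference between the 2 effects picked out 25 of 8404 genes, 22 of them with a lower effect on the newer type. Among these genes, picked because their effects differ, 24 had effects of opposite sign and CG8630 did not. In 22 genes the DEX arrays were higher on the older and lower on the newer type. The clock genes among them were vri, with a difference between effects of -6.11 ± 0.34 (SE, adjusted p = 0.0011), cwo at -5.81 ± 0.72 (adjusted p = 0.0398) and Pdp1 at -4.48 ± 0.29 (adjusted p = 0.0020). MFS14, uncertain like vri and Pdp1 through its _s_at probe set on the newer type, showed the largest, -6.85 ± 0.30 (adjusted p = 9.6e-04), and among other genes phu was at -5.38, Orct2 at -4.95 and Tret1-1 at -4.84; for CG15096 the size is not resolved, its EtOH arrays being near the floor. The genes hry, E(spl)m3-HLH, E(spl)mbeta-HLH and E(spl)m6-BFM, from the list of Hairy/E(spl)-type repressors and Notch targets, differed by -2.71, -2.65, -2.88 and -2.27, and Hex-A, for the first enzyme of glycolysis, by -2.66. By its brightest probe sets the clock gene tim did not pass (adjusted p = 0.372). These had an SD of 0.87 with DEX on the older type and 1.81 with V on the newer. Its other probe sets had DEX effects of 1.96 and -0.04 on the older type and -2.54, a size not resolved, on the newer. They were not tested against each other. With plain _at probe sets alone 15 of the 25 could be tested, and 12 of these and 0 other genes passed. Leaving out EtOH replicate 1 or 2 gave 7 or 11 genes, DEX replicate 2 of the older type 15, V replicate 1 or 2 gave 89 or 42, and DEX replicate 1 or 2 of the newer type 65 or 47.

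**Figure D3:**
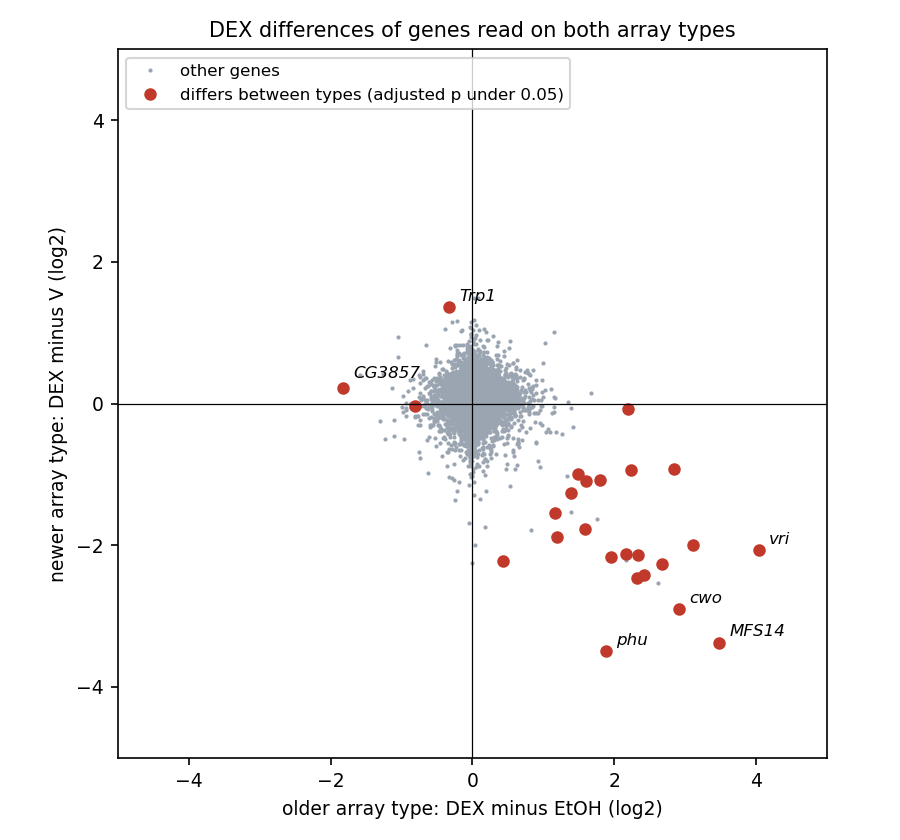
Each point is 1 of 8404 genes read on both array types, with the log2 difference of DEX from EtOH on the older type (horizontal axis) against that of DEX from V on the newer type (vertical axis). Red points mark the 25 genes whose effects differ, 22 of which lie to the right of 0 and below it.

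With both array types in a single fit, no common change with DEX was called among the core clock genes. This fit has no interaction term, so opposite effects on the types enter its residual spread, its SEs and its p-values. For vri the SE was 1.12, against 0.24 for the older type's effect in the fit with an interaction term. The differences were 0.99 ± 1.12 (SE) for vri, 0.04 ± 1.07 for tim, 0.10 ± 0.82 for Pdp1, 0.01 ± 1.11 for cwo, -0.28 ± 0.26 for Clk, 0.02 ± 0.12 for cyc and -0.02 ± 0.04 for per, which lay near the floor on the older type, with adjusted p of at least 0.901. Of 8404 genes, limma called 0, with a smallest adjusted p of 0.901, and 308 lay at an unadjusted p under 0.05 where 420 are expected by chance. The 10 genes with the smallest p did not pass. Akt, for a kinase of insulin signalling, had the largest difference of these, 1.08 ± 0.16 (uncertain, _s_at on the newer type), with DEX arrays higher on both types (1.15 and 1.01). CG9932 was at -0.73 and Amun (uncertain, _s_at) at -0.75, and exu (uncertain, _s_at, and at 3.66 with EtOH on the older type), CG5934, Cyp12c1, CG5854, Mlf, shrb and mRpL33 lay between 0.45 and 0.62. An F test that ignores direction, added later, called 20 genes, 18 of them with opposite signs on the types.

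No fixed gene list was called in the fit of both types: 0 of 21 passed camera and 0 passed fry, and 2 lay at an unadjusted p under 0.05. Ribosomal proteins came closest, with 25 of 35 measured members positive and an adjusted p of 0.0707 (RpS15 0.18, RpL37-1 0.16), then the cell cycle list with 13 of 15 positive and 0.327 (Mcm3 0.34, Mcm5 0.29). The adjusted p was 0.657 for fat body and gut markers, 0.707 for rhythmic clock output (Usp8 0.44), heat shock and haemocyte markers (NimC1 0.24, Fer1HCH 0.16), and 0.905 for the other 15 lists. Among members of these lists, Bruce, an inhibitor of apoptosis gene, stood at -0.47, Cyp12d1-d at -0.44, Cyp6a19 at -0.26, Pp1-87B at 0.29 and ERp60 at 0.23, none of which passed. For the core clock list the median (0.02) and mean (0.12) were positive and the camera direction was down, with 0 members called over all genes and 0 adjusted over the list alone.

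By array type, the core clock list and that of Hairy/E(spl)-type repressors with Notch targets, called Hairy/E(spl) here, moved in opposite directions. On the older type, camera placed the core clock list higher (adjusted p = 1.8e-07, and adjusted p = 0.417 with an estimated correlation), with 3 of 6 members called over all genes and 4 higher and 1 lower, Clk, when adjusted over the list alone. The Hairy/E(spl) list was also higher (adjusted p = 1.8e-07 and 0.417), with 2 of 7 members called and 3 adjusted over the list alone. So were glycolysis (0.0268 and 0.996) and ribosomal proteins (0.0238 and 0.629). These 2 lists had 0 of 8 and 0 of 33 members called over all genes, and 1 and 0 adjusted over the list alone. On the newer type, core clock was lower (adjusted p = 0.0020, and adjusted p = 0.708 with an estimated correlation), with 0 of 7 members called and 3 adjusted over the list alone, and so was Hairy/E(spl) (3.6e-08 and 0.529), with 0 of 6 called and 4 adjusted over the list alone. In the test of the difference, core clock (1.7e-06 and 0.165), Hairy/E(spl) (2.2e-14 and 0.0245), glycolysis (0.0166 and 0.397) and ER stress (0.0210 and 0.685) were lower on the newer type. Hairy/E(spl) alone held with an estimated correlation. Members called over all genes were 3 of 7 for core clock and 4 of 7 for Hairy/E(spl). For glycolysis 1 of 8 was called, Hex-A at -2.66, and the list median was -0.20. For ER stress it was 1 of 11, Gadd45 at -3.18, with a list median of -0.17. By fry, which asks if the members of a list move one way on balance, core clock passed on the older type (adjusted p = 0.0441) and in the difference (0.0044) but not on the newer type (0.108). Hairy/E(spl) passed in all 3 (0.0441, 1.8e-04 and 0.0022 in that order). The 5 lists of cell type markers had 0 calls in any of the 4 fits.

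Across all 8404 genes the DEX effects on the types correlated at Pearson r = -0.175 and Spearman rho = 0.0509, a value across genes, which are not independent replicates. Other pairings of the arrays within each type gave r between -0.0683 and 0.0746 and rho between -0.0932 and 0.0842, so that rho lay within its range and r outside. Among the 56 genes with an effect of at least 1 in size on the older type, 44 had the opposite sign on the newer and r was -0.664. Of the 25 with such an effect on both types, 24 had opposite signs.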

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

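The 25 genes below are listed because a direct test, fixed beforehand, found their DEX effects to differ between array types. The tests of explanations in this part were chosen, or their bounds set, after the result was seen. The effect on the newer type minus that on the older was -6.85 for MFS14, -6.11 for vri, -5.81 for cwo, -5.38 for phu, -5.10 for CG15096, -4.95 for Orct2, -4.84 for Tret1-1, -4.78 for CG3764, -4.48 for Pdp1, -4.29 for CG6231 and -4.12 for CG3348. It was -3.76 for CG13868, -3.36 for CG4766, -3.18 for Gadd45, -3.07 for Rim2, -2.88 for E(spl)mbeta-HLH, -2.71 for hry, -2.70 for CG7530, -2.66 for Hex-A, -2.65 for E(spl)m3-HLH, -2.48 for CtsL1 and -2.27 for E(spl)m6-BFM. It was 0.78 for CG8630, 1.69 for Trp1 and 2.05 for CG3857. The values of MFS14, vri, Pdp1, CtsL1, CG7530 and CG6231 are uncertain, because an _s_at probe set reads them on the newer type, and the sizes for CG15096 and CG8630 are not resolved, the EtOH arrays of the former and the older type's DEX arrays of the latter being near the floor. The call of CG8630 is uncertain too, since its EtOH arrays held the same value.

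The pattern is that genes higher with DEX on the older type were lower on arrays labelled DEX on the newer type. Of 17 genes called higher on the older type and read on both, 16 had both DEX-labelled arrays under both V-labelled arrays on the newer type. A single gene has a chance of 16.7% of this order, but all 17 were read on the same arrays, so they are not independent events. The exception was Fmo-2 at 0.15. A single mislabelled array would leave the groups overlapping, but they separated in those 16. The median newer-type effect was 0.00238 over all genes and -2.07 for the 17, so no shift common to all genes was left in the values. Normalisation by quantiles holds the median over all genes near 0, so it cannot tell whether scaling had a part. Probe sets shared between genes are argued against for the 9 genes read by plain _at probe sets on both types: 8 were lower, among them cwo at -2.90, CG3764 at -2.46 and Orct2 at -2.26, though E(spl)m6-BFM by as little as -0.08. The exception was again Fmo-2, and a stricter bound set at first had asked for all 9. For the other 8 genes, vri, tim, Pdp1 and MFS14 among them, this stays open, since 0 have a plain probe set on both types. An exchange of the V and DEX labels in the newer table may account for the 16 genes, and so may an exchange in the older table, which this count cannot separate; CLK is known to activate vri, tim, Pdp1 and cwo, the direction the older table's labels give. A true difference between the experiments, in control, culture or dose, cannot be told apart from array type, because 0 control groups were read on both types.

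The difference between types has groups of 2 arrays per type, and 18 splits of the 8 arrays keep 2 and 2 of each type. The real split gave 25 genes and the highest other gave 1; with as few as 18 splits no share under 0.05 can be reached. The first count took in all 34 splits into 4 and 4 that could be fitted, of which 11 gave as many, the highest other 147. The other 10 of those put 3 and 1 arrays of each type on either side and leave groups of a single array with no spread of their own, so they are not comparable. For the fit of both types the real split gave 0 genes, so all 34 splits gave as many. The highest other gave 18, and it was the split that exchanges the newer table's groups. That split sets the arrays against each other as the difference between types does, so its 18 genes are no separate evidence.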

How the results depend on the processing

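The alternatives added after seeing the data were the natural log scale, the F test, the list tests per type and the effects with the variance of all 8 arrays. Calls on the older type numbered 27; they became 73 with no filter, 13 with a minimum log2 of 6, 12 without the intensity trend, 4 with quantile normalisation repeated, 8 with median centring, 42 at an adjusted p of 0.1 and 14 on the natural log scale with a minimum of 4 there, a stricter filter of 54.6 on the deposited scale in place of 16, and were 0 without an EtOH array. Without a DEX array they were 262 and 447, which are not comparable, because those fits took the variance as known from all probe sets. A lone array is assumed to vary like the other group. Higher and lower calls were 22 and 5, but 4 and 0 after quantile normalisation and 8 and 0 after median centring. The newer type and the fit of both types kept 0 calls under each alternative fixed beforehand, and the F test gave 20 in the latter. With the variance of all 8 arrays, 14 of 8404 genes passed on the newer type, 1 higher and 13 lower on arrays labelled DEX. On the older type 14 passed in that fit, 12 higher and 2 lower. Of the core clock genes, 0 passed in the fit of both types, 3 on the older type alone by the brightest probe set of each gene, and 2 on either type with the variance of all 8 arrays. Genes whose effect differs numbered 25, 12 with plain _at probe sets alone, 7 to 89 with an array left out, and 20 to 28 otherwise. For gene lists the count of 0 became 1 with no filter (ribosomal proteins, adjusted p = 0.0017, and 0.996 with an estimated correlation), 1 in 3 of the 8 fits with an array left out (ribosomal proteins in 2 and cell cycle in 1; at least 0.931 with an estimated correlation), and 4, 2 and 4 on the older type, the newer type and their difference, or 0, 0 and 1 with an estimated correlation. The correlation of -0.175 was -0.229 at a minimum log2 of 6, -0.0990 with plain _at probe sets, and -0.204 to -0.0949 with an array left out. The cause of these shifts was not tested, beyond the fewer or more features and arrays entering each fit.

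Of the single-gene values that had a call, 0 reversed, and 22 of 1374 values without a call changed sign; on the older type 225 were as before, 130 lost and 4 gained the threshold, and for the difference between types 310 were as before and 97 lost it. The difference of replicate 1 from replicate 2 in the control group was correlated, across probe sets, with that in the DEX group. The value was 0.264 on the older and -0.0231 on the newer type. The numbers were not taken to pair arrays on either type, though the value on the older type leaves a pairing there open. With the replicate number as a block the calls were 34, 0 and 0 on the older type, the newer type and both, and 0 for the clock genes. On the older type 25 of the 27 calls were shared with the block, and CG3764 (adjusted p = 0.0512) and the unnamed probe set that fell (0.0606) were not. Split by replicate number, the older type had 883 probe sets at an unadjusted p under 0.05, and 0 past the threshold. That was more than the 600 for DEX and the 512 expected by chance, and the remaining split of 2 and 2 arrays gave 184. Values near the floor of GCRMA carry little signal over background, which limits per and cry, tim on the newer arrays labelled DEX, CG15096 and exu on the EtOH arrays, and CG8630 on the older DEX arrays.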

Other observations

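The tests in this part were chosen after the result was seen. Some of the 25 genes whose effect differs between array types lie next to each other. By gene order in the RefSeq annotation, MFS14 and CG15096 are neighbours among the tested genes, and E(spl)mbeta-HLH, E(spl)m3-HLH and E(spl)m6-BFM lie within the E(spl) complex, a cluster of Notch-responsive genes. A hypothesis is that neighbouring genes share the response, which these data leave open. Of the 3 pairs within 3 places of each other, 2 lie in the E(spl) complex, whose presence among the genes prompted the question, and 1 lies outside it, where 19.2% of 10000 random sets of 25 tested genes had at least 1 pair. MFS14 and CG15096 both belong to transporter families, and cross-hybridisation between them was not tested.

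The deposited values exceed what a scanner can give. A candidate explanation is that they were raised to base e instead of base 2, since the hybridisation controls rose against nominal concentration with a mean slope of 0.950 on the natural log and 1.37 on log2, and a slope near 1 is what a linear response gives. This slope joins 4 different probe sets, whose unequal binding also bears on it. The log2 step from BioD to Cre was 4.54 on the older and 3.04 on the newer type, and that from BioB to BioC was 1.26 and 1.87. No biological explanation was tested for this. On that base, the older-type differences are 2.80 for vri, 1.62 for Pdp1 and 1.36 for the called probe set of tim.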
